A study of Mus musculus with 63 samples.

How the data were processed

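The starting point was the table of RSEM expected counts that the authors deposited for each of 63 libraries. Per the submitters' processing notes, reads were quantified with RSEM against mm9. The RSEM version, the aligner, any read filters and the strand setting are not stated. The libraries were made with the Lexogen SENSE mRNA-Seq kit from polyadenylated RNA, per the submitters' protocol. Per the same protocol, embryonic stem cells grew on mouse embryonic fibroblast feeders, the 2i medium held PD0325901 at 1 µM and CHIR99021 at 3 µM with LIF at 10 ng/ml, the serum medium held 15% serum with LIF at 10 ng/ml, and NPCs were made over 4 days from serum cells passaged without feeders. Replicate 3 of the Ctrl NPC group carries no growth protocol.

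Each table had 24990 rows, of which 23822 were matched by gene id, 1139 by transcript accession and 28 had no name. Rows that merge several genes numbered 375 and held 1.88% to 2.37% of the counts. Between 4.65% and 7.86% of values per library were not whole numbers, and all were rounded before the count models. The unnamed row with the most counts held 0.668% to 6.041% of a library. Depth ran from 7566621 to 18553303 counts. No library was a copy of another: the chi-square per gene was at least 5.57 over the 63 pairs within groups and at least 4.91 over the 1890 pairs between groups. None was left out. A chromosome was known for 23643 genes.

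Differential expression was tested with edgeR 4.0.16 by quasi-likelihood F tests, after TMM scaling and filterByExpr, with Benjamini-Hochberg adjustment at 0.05, in R 4.3.3. The standard error was the absolute log2 fold change divided by the square root of F. Each genotype comparison used 1 fit per state with all 15 libraries and 1 mean per line. The pKO effect was the mean of the pKO1 and pKO2 line means minus the mean of the WT1 and WT2 line means, and pInv was its line mean minus the WT mean. The knockdown comparison used 9 libraries per state, and the perturbation libraries were never fitted with the genotype libraries. State comparisons used the 18 WT libraries. Interactions between state and genotype used all 45 genotype libraries, and that for knockdown used 18. Gene lists, 28 in all with 401 of 402 members matched, were tested with camera in limma 3.58.1 using a preset correlation of 0.01, beside the estimated correlation, and adjusted over 448 tests. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for preparation and figures.

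Genes were named by a fixed rule. Eomes, Platr11 and the genes next to Eomes were named in every comparison. The 6 largest rises and 6 largest falls were named among genes past an adjusted p of 0.05 with a mean of at least 1 CPM and with every line mean of one arm on the same side of every line mean of the other. Up to 3 members of each list past 0.05 were named by smallest p, with any member needed to say that a list did not move.

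The design, the lines compared, the filter, the named-gene rule and the first set of alternatives were set before the data were examined. Those alternatives were DESeq2 1.42.0, RLE scaling, no low-count filter, each line alone, the lines as replicates, a block for the replicate number, and leaving out each library. Added after seeing the data were a feeder score as a covariate, with and without the block, leaving out the libraries numbered 1 or 3, and leaving out the genes of chromosomes 8 and 11. All tests of explanations were chosen after the result was seen.

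Whether replicate numbers pair the libraries was checked by correlating residuals of libraries with the same number in different lines. In 2i all 30 pairs were correlated, from 0.246 to 0.707 with a median of 0.451, and the lowest of the knockdown pairs was 0.304 in serum, 0.249 in NPCs and 0.223 within states in the fit over both states, which has a block per number and state. Across states 24 of 27 knockdown pairs passed 0.1 and the lowest was 0.031. In serum 29 of 30 genotype pairs passed 0.1, in NPCs 17 of 30, with the lowest at −0.346, in the WT state set 8 of 9 and in the joint set 72 of 90. The numbers were taken to pair a set where every pair passed 0.1, which the serum set missed only by its lowest pair, at 0.097. Values with a replicate block are therefore given beside the results for 2i and for knockdown, such as 2925 calls for pKO in 2i. The pKO counts in serum are given with the block too.

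The pipeline was tested on simulated data with 200 changed genes, 67, 67 and 66 of them at 1.5-fold, 2-fold and 4-fold. The simulated libraries held no differences between lines and no shared replicate effects, so the false calls below do not cover either. For pKO against WT it recovered 31, 53 and 64 of these in 2i with 9 false calls, 15, 43 and 62 in serum with 8, and 21, 45 and 62 in NPCs with 7. For pInv it recovered 29, 43 and 58 in 2i with 5 false calls, 9, 43 and 51 in serum with 4, and 6, 29 and 57 in NPCs with 1. For knockdown it recovered 1, 33 and 58 in serum with 6 false calls and 5, 36 and 57 in NPCs with 9, and for its interaction 2, 13 and 43 with 5. For the pKO interaction it recovered 10, 27 and 46 with 6. Scaling by RLE instead of TMM shifted the median log2 fold change of a comparison by at most 0.017.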

Results

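Polyadenylated RNA was sequenced from R1 mouse embryonic stem cells and from neural progenitor cells (NPCs) made from them, to ask how the Meteor long non-coding RNA locus, named in the series title, relates to expression of Eomes. Eomes, on chromosome 9, encodes a T-box transcription factor needed for mesoderm and endoderm formation. There were 63 libraries in 21 groups of 3. The genotype series held 5 lines: 2 wild-type lines (WT1, WT2), 2 lines without the Meteor promoter (pKO1, pKO2) and 1 line with the promoter inverted (pInv). Each was grown in 2i medium (inhibitors of MEK and GSK3 with LIF), in serum with LIF, and as NPCs. The perturbation series held an empty-vector control (Ctrl) and a pair of CRISPR knockdown lines (KD1, KD2) in serum and as NPCs. Total counts ran from 7566621 to 18553303 per library. Nothing in the labels says that the 3 libraries of a group came from separate cultures. Except where lines serve as replicates, the adjusted p-values measure the spread between the libraries of a line. They do not cover the spread between lines. Values are library-scaled counts (CPM) with SD, or log2 fold changes with standard error (SE). Intervals and floors cover counting error only.

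Meteor is not a symbol in the deposited tables. The readout used for its locus was Platr11, a non-coding RNA that lies next to Eomes in the reference annotation, though no source at hand states that it is the same transcript. Platr11 was 24.5 ± 2.17 CPM in WT cells in 2i (SD, n = 6), 9.34 ± 2.36 in serum and 5.98 ± 1.05 in NPCs. In the pKO lines it kept 0.311% of the WT level in 2i (95% exact interval 0.101 to 0.728), 0.754% in serum (0.244 to 1.77) and 1.39% in NPCs (0.507 to 3.04). In pInv it kept 0.961% in 2i (0.414 to 1.9) and 0.933% in serum, from 3 counts (0.192 to 2.74). No Platr11 count was found in the 3 pInv NPC libraries, which is at least 76.7-fold lower than WT when a floor of 3 counts is set over the group. The KD lines kept 9.02% of the Ctrl level in serum (7.25 to 11.1) and 14.3% in NPCs (11.9 to 17.1). Every WT library, at 4.56 CPM or more, lay above every pKO and pInv library, at 0.367 or less. Platr11 was near 0 in both edited genotypes, so it could not show an exchange between pKO and pInv. The other gene beside Platr11, Cmc1, did not pass the test in any genotype or knockdown comparison, and nor did Golga4, a further neighbour of Eomes.

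**Figure D1:**
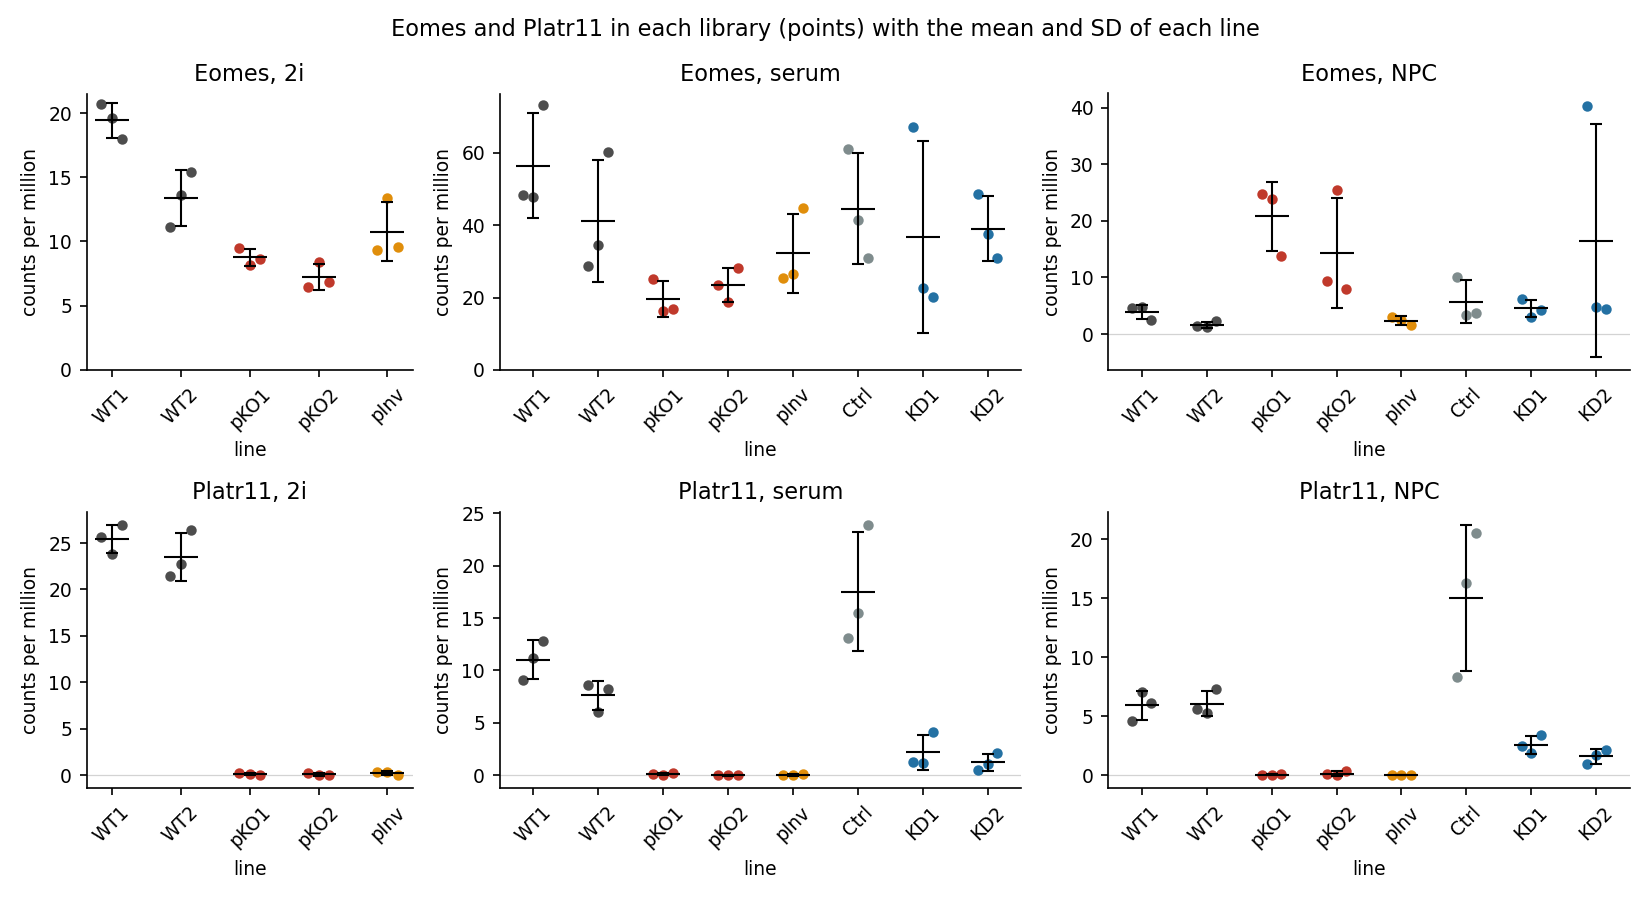
CPM of Eomes (top) and Platr11 (bottom) in every library, by line and culture state, with bars for the mean and SD of 3 libraries. All 6 pKO libraries lay below all 6 WT libraries for Eomes in 2i and serum and above them in NPCs, and KD2 replicate 1 reached 40.3 CPM in NPCs.

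The WT lines gave the background of each state. Eomes was 16.4 ± 3.67 CPM in 2i, 48.8 ± 16.4 in serum and 2.78 ± 1.52 in NPCs (SD, n = 6 each). From 2i to serum it rose (log2 fold change 1.55 ± 0.19 SE, adjusted p = 2e-06), while Platr11 fell (−1.44 ± 0.15). Of 15146 genes tested, 4466 rose and 4470 fell. Serum cells gained markers of the formative and primed epiblast, with 13 of 14 members up, among them Dnmt3b (3.09 ± 0.13) and Lef1 (3.13 ± 0.16), and Fgf5, an epiblast growth factor, had one of the largest rises (10.86 ± 0.58). Naive pluripotency genes went the other way, with 11 of 15 down and 1 up, including Tbx3 (−3.91 ± 0.12) and Tcl1 (−1.64 ± 0.11). Primitive streak and mesendoderm genes rose in serum (13 up and 3 down of 20), with T at 7.64 ± 0.64, Fgf8 at 7.07 ± 0.52 and Wnt3 at 5.45 ± 0.36. ERK target genes, held down by the MEK inhibitor in 2i, rose for 8 of 12, such as Spry4 (4.85 ± 0.25). Imprinted genes rose for 17 of 20, led by Peg10 (4.65 ± 0.20), and 9 of 12 germline genes fell, including Dazl (−5.22 ± 0.28). Cholesterol synthesis genes fell for 12 of 15. Fibroblast genes of the feeder layer moved with these groups, with 15 of 20 up in serum. These 8 lists were called with a preset correlation between genes, and none was called with an estimated one (smallest adjusted p = 0.0816 with an estimated correlation, for the epiblast list).

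From serum to NPCs, Eomes fell in WT cells (−4.35 ± 0.23, adjusted p = 2.9e-11), and Platr11 fell less (−0.71 ± 0.15). Of the same 15146 genes, 4852 rose and 5194 fell. Neural progenitor genes rose for 16 of 21, including Sox1 (8.46 ± 0.35), and neuronal genes rose for 13 of 18, such as Dcx (4.81 ± 0.38). The glutamate receptor gene Grin2b rose by 9.89 ± 0.45. Naive genes fell for 14 of 15, with Tcl1 at −4.57 ± 0.14 and Zfp42 at −3.65 ± 0.16, and Pou5f1 fell by 1.09 ± 0.11. Primitive streak genes fell for 18 of 20, with Mixl1 at −6.04 ± 0.47 and T at −5.67 ± 0.55. Nodal pathway genes fell for 9 of 11, including Lefty2 (−4.98 ± 0.23). Cholesterol synthesis genes rose for 13 of 15, with Msmo1 at 2.49 ± 0.13. All 20 feeder fibroblast genes fell, Col1a1 by 5.50 ± 0.29, and the macrophage genes Lyz2 (−12.51 ± 0.81) and Mpeg1 (−11.21 ± 0.74) were among the largest falls, in cultures whose protocol removed the feeders. None of the 7 lists named here was called with an estimated correlation, the nearest being the neuronal and Nodal lists (adjusted p = 0.0514 with an estimated correlation for each).

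Loss of the promoter was compared with WT first in 2i. Eomes fell from 16.4 to 8 ± 1.13 CPM (log2 fold change −0.98 ± 0.12, adjusted p = 0.000318), with all 6 pKO libraries below all 6 WT libraries. Dnmt3l, a cofactor of DNA methylation, fell (−1.33 ± 0.14), as did the epiblast growth factor Fgf15 (−1.58 ± 0.23) and Nodal (−0.63 ± 0.14), the ligand upstream of Eomes in the embryo. Ldhb, a lactate dehydrogenase subunit, rose (1.38 ± 0.10, adjusted p = 2.7e-06), and so did the ion channel gene Trpm1 (1.49 ± 0.16) and the stress regulator Atf4 (0.53 ± 0.06). Of 13931 genes tested, 458 rose and 815 fell, but only 12 of the rises and 160 of the falls passed 2-fold. The largest falls after Platr11 were Aqp5, a water channel (−2.54 ± 0.60), the chromosome 11 genes Alox12b (−2.16 ± 0.35) and Ptchd3 (−2.07 ± 0.35), and Tdrkh, which acts in the piRNA pathway (−2.05 ± 0.29). Epithelial keratin Krt8 (−1.18 ± 0.16) and its regulator Grhl2 (−0.86 ± 0.14) were the 2 of 8 surface ectoderm genes that passed, and 4 fell when adjusted over the list alone. Among 15 hypoxia and glycolysis genes 4 rose and 1 fell, including Hk2 (0.54 ± 0.06) and Eno1 (0.24 ± 0.05), and 6 rose when adjusted over the list alone. The ERK targets Etv4 (1.10 ± 0.11) and Dusp6 (0.72 ± 0.15) rose and Egr1 fell (−0.29 ± 0.07), with 5 of 12 up when adjusted over the list alone. Of 10 genes of 2-cell-like cells 3 fell and 5 did when adjusted over the list alone, among them Usp17la (−1.44 ± 0.32), a member of a multigene family whose reads are uncertain. Of 13 ATF4 targets 2 rose. These 5 lists were called (adjusted p = 0.000151 for 2-cell-like, 0.00115 for ATF4 targets, 0.00213 for surface ectoderm, 0.0271 for hypoxia and 0.0391 for ERK targets), but adjusted p = 0.157, 0.183, 0.157, 0.674 and 0.678 with an estimated correlation. Naive genes were mixed, with Klf5 (0.51 ± 0.08), Nr0b1 (0.43 ± 0.08) and 2 more up and 1 down of 15, and the list was not called (adjusted p = 0.174). Of 19 imprinted genes 4 rose, including Rian (0.67 ± 0.13) and Mirg, counted together with microRNA genes (0.96 ± 0.13), and 1 fell, and the list was not called (adjusted p = 0.441). Of 10 primitive streak genes Sp5 passed as a rise (1.03 ± 0.25) and none passed as a fall. The neuronal genes Elavl3 (−1.55 ± 0.25) and Mapt (−0.61 ± 0.12) fell, out of 13 measured, and Hoxa9 fell (−1.84 ± 0.35) among 15 Hox genes.

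The 2i result depended on the line used as control. WT1 and WT2 differed from each other at 2536 genes, more than pKO differed from WT, and Eomes was among them (0.53 ± 0.16, adjusted p = 0.0309). In the same fit the lines regrouped as WT1 and pKO2 against WT2 and pKO1 gave 1467 calls. With only WT1 as control Etv4 (−0.23) and the naive gene Tfcp2l1 (−0.07, against 0.35 ± 0.06 with both) changed direction while Eomes (−1.25), Dnmt3l, Ldhb, Atf4 and Hk2 passed against either line. In 2i the replicate numbers paired the libraries, and with the replicate block 2925 genes passed, among them all 1273, feeder fibroblast and interferon genes were called (adjusted p = 0.0246 and 0.016, but adjusted p = 0.602 and 0.392 with an estimated correlation), and ERK targets were not (adjusted p = 0.0557). With the lines as replicates the Eomes call was lost (−1.01, adjusted p = 0.884). The count fell to between 704 and 838 when WT2 replicate 1, pKO1 replicate 2 or 3, or pKO2 replicate 2 or 3 was left out. The call for Egr1 was lost without pKO2 replicate 2 (−0.27) and that for Sp5 without pKO1 or pKO2 replicate 3 (0.89 and 0.97).

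The same comparison was then made in serum. Eomes fell from 48.8 to 21.5 ± 4.89 CPM (−1.13 ± 0.21, adjusted p = 0.00818), again with all 6 pKO libraries below all 6 WT libraries. Primitive streak regulators fell with it: Evx1 (−1.90 ± 0.36), Lhx1 (−2.54 ± 0.49) and the retinoic acid hydroxylase Cyp26a1 (−2.22 ± 0.37). The naive factor Tbx3 rose (1.20 ± 0.13, adjusted p = 0.000183), as did the pluripotency cofactor Tcl1 (0.80 ± 0.13). Genes of the Zscan4 family, which mark the 2-cell-like state, rose the most, with Zscan4b at 3.11 ± 0.31 and Zscan4d at 3.09 ± 0.34, although reads can be shared between these near-identical copies. Of 14197 genes, 252 rose and 595 fell, 105 and 167 of them past 2-fold. With the replicate block 1504 rose and 1384 fell, so the excess of falls was lost. Among 18 primitive streak genes 6 fell and none rose, with 15 down and 1 up when adjusted over the list alone (list adjusted p = 7.06e-07, and adjusted p = 0.464 with an estimated correlation). The 2-cell-like list had 11 of 12 members up and stayed called either way (adjusted p = 9.77e-19, and adjusted p = 0.0485 with an estimated correlation). Wnt targets had 4 of 12 down, including Tcf7 (−0.97 ± 0.16) and Znrf3 (−0.43 ± 0.09), both on chromosome 11, with 8 down and 2 up when adjusted over the list alone. Definitive endoderm genes had 3 of 10 down, such as Krt19 (−1.84 ± 0.40) and Sox17 (−1.77 ± 0.43). Naive genes had 3 of 15 up, with Nr0b1 (0.52 ± 0.14) beside Tbx3 and Tcl1, and 7 when adjusted over the list alone. The neural genes Pax6 (1.08 ± 0.28) and Onecut2 (1.46 ± 0.32) and the neurogenic factor Insm1 (1.38 ± 0.35) rose singly, and the neural progenitor list was not called (adjusted p = 0.0736). Of 20 Hox genes Hoxb1 fell (−2.20 ± 0.49) and Hoxb3 rose (1.08 ± 0.30), and of 9 neural crest genes Tfap2a rose (1.01 ± 0.23). Cholesterol synthesis genes had 2 of 15 down, including Dhcr7 (−0.61 ± 0.12). The Wnt, endoderm, naive, Hox, neural crest and cholesterol lists were called at adjusted p = 0.00519, 0.0068, 0.00227, 0.000252, 0.00126 and 0.00637, and had adjusted p = 0.481, 0.564, 0.474, 0.678, 0.412 and 0.564 with an estimated correlation. Feeder fibroblast genes moved with all of these groups (median 0.77 over 20 genes, none passing singly, list adjusted p = 0.000126), but adjusted p = 0.678 with an estimated correlation. The largest falls besides Platr11 included the apelin receptor Aplnr (−3.31 ± 0.73) and X-linked Xlr3a, Ct55 and Nxf3 (−2.84 ± 0.31, −2.79 ± 0.39 and −2.60 ± 0.24).

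Single libraries carried much of the serum count, which was 307 without WT1 replicate 3, 350 without WT2 replicate 3, 1370 without pKO2 replicate 3, and between 448 and 522 without WT1 replicate 2, pKO1 replicate 1 or 2, or pKO2 replicate 2. Eomes passed in all 12 of these fits, but not with the lines as replicates (−1.17, adjusted p = 0.0791). Krt19 lost its call without WT1 replicate 3 (−1.6), Onecut2 without WT1 replicate 2 (1.34), Hoxb1 without pKO1 replicate 2 or WT1 replicate 3, and Aplnr without pKO1 replicate 2, WT1 replicate 3 or WT2 replicate 3. Tfap2a lost it in 4 of the 12 fits, Sox17 in 5, Pax6 and Insm1 in 7, and Nr0b1 and Hoxb3 in 10.

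In NPCs the direction of Eomes turned over. It was 17.5 ± 8.09 CPM in pKO against 2.78 ± 1.52 in WT (SD, n = 6 each, log2 fold change 2.81 ± 0.32, adjusted p = 0.000208), and every pKO library, from 7.97 to 25.5, lay above the highest WT library at 4.73. Nodal (2.35 ± 0.28, adjusted p = 0.000288) and its co-receptor gene Tdgf1 (1.29 ± 0.16) rose. So did the streak genes T (3.47 ± 0.66), Wnt3 (2.45 ± 0.33), Fgf8 (3.82 ± 0.57) and Sp5 (4.45 ± 0.80), the posterior factor Cdx2 (5.38 ± 1.09) and the endoderm factors Foxa2 (3.69 ± 0.69) and Gata4 (2.25 ± 0.33). Of 14511 genes tested, 502 rose and 669 fell, 163 and 187 past 2-fold. Primitive streak genes rose for 9 of 14 and fell for none (list adjusted p = 2.69e-07, but adjusted p = 0.183 with an estimated correlation). Nodal pathway genes rose for 6 of 11, and for 8 when adjusted over the list alone (list adjusted p = 3.4e-06, but adjusted p = 0.106 with an estimated correlation). Definitive endoderm genes rose for 5 of 10, and for 6 when adjusted over the list alone (list adjusted p = 0.000252, but adjusted p = 0.124 with an estimated correlation). Extraembryonic endoderm gained 4 of 14, with the receptor gene Cubn (1.87 ± 0.36), and core pluripotency gained 4 of 12, with Pou5f1 (0.63 ± 0.16) and L1td1 (0.78 ± 0.22) beside Tdgf1. ERK targets gained 4 of 12, including Spry4 (1.08 ± 0.24) and Dusp6 (0.52 ± 0.10), trophoblast genes 2 of 9, surface ectoderm genes 2 of 7, with Grhl2 (1.03 ± 0.19), and Hox genes 2 of 10, with Hoxb1 (2.47 ± 0.57) and Hoxa5 (4.38 ± 0.97). Interferon genes lost Ifit2 (−1.16 ± 0.26) of 9. These 6 lists were called at adjusted p = 0.00686, 0.00969, 0.0301, 0.0343, 0.0118 and 0.0278, with 0.0309 for the interferon list, but adjusted p = 0.402, 0.464, 0.389, 0.398, 0.412, 0.678 and 0.389 with an estimated correlation. Genes of the 2-cell-like state rose for 10 of 11, with Zscan4f at 2.59 ± 0.35 (list adjusted p = 1.1e-11, but adjusted p = 0.0514 with an estimated correlation). The neural programme did not pass as a list: 1 of 22 neural progenitor genes rose, the hindbrain and roof plate gene Zic1 (2.77 ± 0.58), and of 18 neuronal genes Elavl3 fell (−0.47 ± 0.14), with list adjusted p = 0.556 and 0.46. Naive pluripotency genes stayed at a median of 0.12 over 15, with Dppa3 down (−1.46 ± 0.29). Feeder fibroblast genes had 1 up and 2 down of 18, and their median was 0.03. Among the largest falls were Xlr3a (−4.68 ± 0.43), the helicase gene Ddx60 (−3.81 ± 0.74) and the deubiquitinase gene Usp26 (−3.35 ± 0.27), and the glucose transporter gene Slc2a1 (−1.13 ± 0.19) and H19 (−2.09 ± 0.45) fell too.

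With WT1 alone as control, T, Fgf8, Sp5, Foxa2 and Cdx2 no longer passed in NPCs, while Eomes (2.16), Nodal, Wnt3 and Gata4 did so against either WT line and with either pKO line. The count was 1921 without WT1 replicate 1 and between 529 and 765 without WT1 replicate 3, WT2 replicate 2 or 3, pKO1 replicate 1 or 3, or pKO2 replicate 2 or 3, and Eomes passed in all 12 of these fits. With the lines as replicates Eomes lost its call (2.71, adjusted p = 0.262), and edgeR called 0 of 16097 genes, with 1852 at an unadjusted p under 0.05, where chance gives 805. Hoxb1 lost its call without pKO1 replicate 1 (1.61), Hoxa5 without pKO1 replicate 1 or WT1 replicate 3, Pou5f1 and L1td1 in 7 of the fits and Elavl3 in 11.

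**Figure D2:**
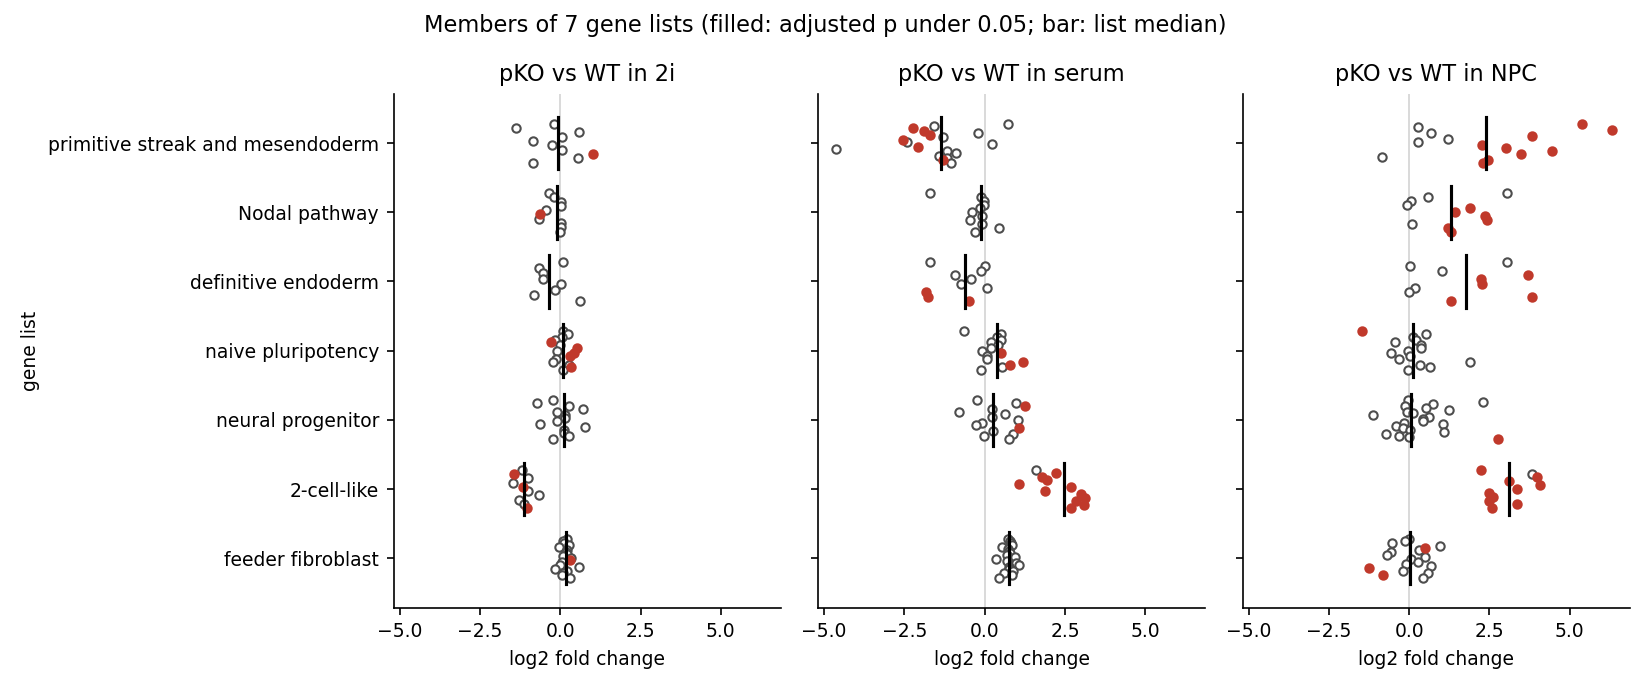
Log2 fold change of each member of 7 gene lists between pKO and WT cells in 2i, serum and NPCs, filled where the adjusted p is under 0.05, with a bar at the list median. Primitive streak genes lay at a median of −1.36 in serum and 2.38 in NPCs, 2-cell-like genes at −1.14, 2.46 and 3.1 in the 3 states, and naive pluripotency genes stayed at 0.12 in NPCs.

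Whether the promoter effect differed between NPCs and serum was tested directly as an interaction over all 45 genotype libraries. The Eomes effect differed by 3.91 ± 0.35 (adjusted p = 2.67e-09). This p-value does not cover the spread between lines, and the interaction was not fitted with the lines as replicates. Within serum and within NPCs Eomes did not pass in such a fit. In a fit with 1 mean per arm, 6 of 100 splits of the libraries called as many genes as the real one (127). Evx1, a posterior streak gene, differed most (8.08 ± 1.05), followed by Cdx2 (6.85 ± 1.08), the antisense transcript Evx1os (6.64 ± 1.17, with uncertain reads) and the Wnt antagonist Dkk1 (6.32 ± 1.10). Of 15682 genes, 315 had a higher effect in NPCs and 326 a lower one. Primitive streak genes were higher for 14 of 20 and lower for none, with T at 4.85 ± 0.72, Fgf8 at 5.51 ± 0.62 and Wnt3 at 3.69 ± 0.38, and the list stayed called either way (adjusted p = 3.78e-23, and adjusted p = 0.017 with an estimated correlation). Nodal pathway genes were higher for 6 of 11 (adjusted p = 2.27e-10, and adjusted p = 0.00325 with an estimated correlation), with Nodal at 2.38 ± 0.30. Definitive endoderm genes were higher for 7 of 10 (adjusted p = 1.84e-09, and adjusted p = 0.017 with an estimated correlation), with Sox17 at 5.54 ± 0.87 and Foxa2 at 4.58 ± 0.70. Wnt targets were higher for 6 of 12 (adjusted p = 4.06e-05, but adjusted p = 0.147 with an estimated correlation). The neural and neurogenic genes Insm1 (−2.31 ± 0.44) and Neurod1 (−1.39 ± 0.34) had a lower effect in NPCs, as did the naive gene Nr0b1 (−1.14 ± 0.25). Feeder fibroblast genes were lower for 2 of 20 (median −0.63, adjusted p = 0.00683, but adjusted p = 0.747 with an estimated correlation). The count was 1086 without WT1 NPC replicate 1, 291 without WT1 NPC replicate 3, and between 356 and 401 without pKO1 or pKO2 serum replicate 2, WT2 serum replicate 3, pKO2 NPC replicate 2 or WT2 NPC replicate 3.

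Across the 3 states, 10 genes rose and 43 fell in pKO at every state, of 12857 tested in all, where independent lists would give 0.269 and 1.52. Of the 43 falls, 30 lay on chromosome 11, which differed as a whole between lines, and 13 did not, where independent lists would give 0.314. The same WT and pKO lines were used in every state, so differences between lines unrelated to the deletion would recur as well. The excess over independent lists cannot tell these from an effect of the deletion. Besides Platr11 the shared falls included Usp26 (−1.46, −2.53 and −3.35 in 2i, serum and NPCs), Tdrkh (−2.05, −0.93 and −1.01), the polycomb gene Phc1 (−0.24, −0.52 and −0.63) and, on chromosome 11, the acyl-CoA synthetase Acsl6 (−1.09, −1.45 and −0.72) and the stress regulator Xbp1 (−0.28, −0.46 and −0.46). The shared rises included the testis helicase D1Pas1 (0.89, 1.29 and 2.1), the transcription factors Sall3 (0.32, 0.68 and 1.64) and Etv1 (0.82, 0.41 and 0.88), and Tenm4 (0.31, 1.11 and 0.65). These genes were chosen after their values were seen.

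Many falls in pKO lay on 1 chromosome. Genes of chromosome 11 had a median log2 fold change of −0.22 in 2i, −0.33 in serum and −0.38 in NPCs against WT, and made up 28.1%, 48.4% and 48.1% of all falls, from 8.3%, 8.1% and 8% of the genes tested. Treated as a set, the chromosome was lower in each state (adjusted p = 0.000341, 0.00646 and 0.00244 with an estimated correlation). In 2i the WT1 line lay at a median deviation of −0.054 ± 0.015 (SD, n = 3), with the pKO and pInv lines, and WT2 stood apart at 0.298 ± 0.007. Chromosome 8 differed between lines too: WT2 and pInv lay high in 2i (0.215 ± 0.017 and 0.261 ± 0.016) and WT1 and pKO2 low (−0.225 ± 0.016 and −0.219 ± 0.015). In pInv chromosome 8 gave 56.8% of the rises in 2i, from 5.2% of genes tested, and its median was 0.26 in 2i, 0.17 in serum and 0.23 in NPCs. Between WT1 and WT2 the chromosome 11 median was −0.35 in 2i, −0.2 in serum and −0.07 in NPCs, and that of chromosome 8 was −0.41, −0.38 and −0.36. Without both chromosomes the pKO calls were 883 in 2i, 367 in serum and 612 in NPCs.

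**Figure D3:**
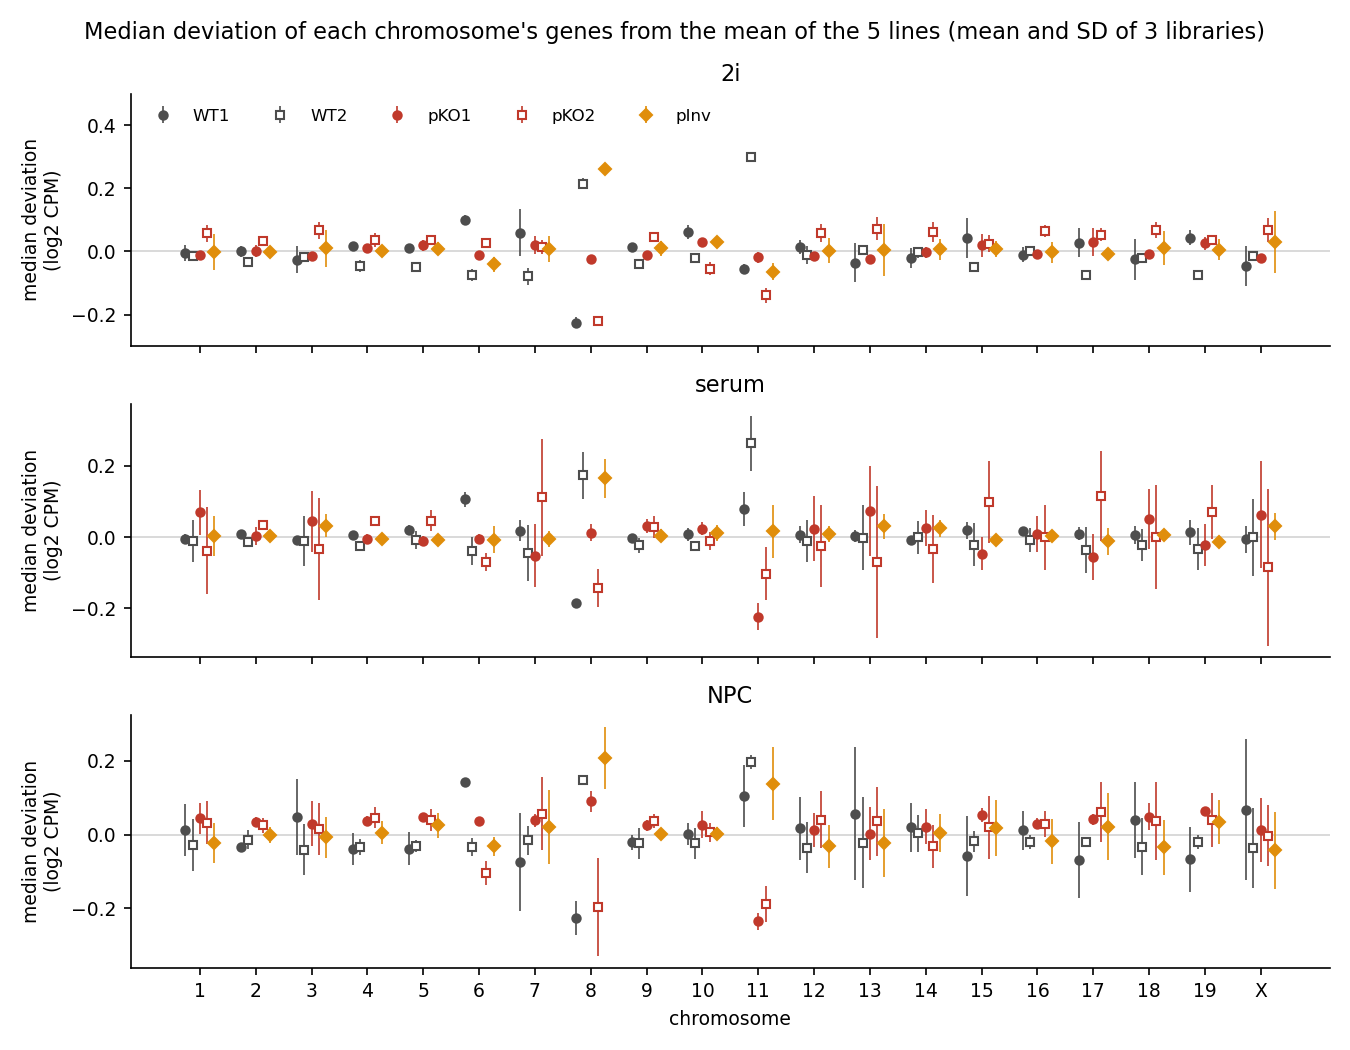
Median deviation of the genes of each chromosome from the mean of the 5 lines, in log2 CPM, as the mean and SD of 3 libraries per line in each state. On chromosome 11 the WT2 line stood at 0.298 in 2i with the other 4 lines at or below −0.019, whereas in NPCs pKO1 (−0.235) and pKO2 (−0.188) lay below the other lines.

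The inversion, which keeps the promoter sequence in place but reversed, was compared with WT in the same way. Eomes was 10.8 ± 2.28 CPM in 2i (SD, n = 3; log2 fold change −0.57 ± 0.14), which missed the threshold (adjusted p = 0.078) but passed with the replicate block (adjusted p = 0.0218) and with DESeq2 (adjusted p = 0.0202). The value depended on the control line, at −0.84 against WT1 (adjusted p = 0.00603) and −0.3 against WT2 (adjusted p = 0.403). Eomes was 32.3 ± 10.9 CPM in serum (−0.57 ± 0.26, adjusted p = 1) and 2.36 ± 0.742 in NPCs (−0.06 ± 0.41, adjusted p = 0.983, with −0.71 against WT1 and 0.59 against WT2). In 2i Dnmt3l (−1.17 ± 0.18), Fgf15 (−1.35 ± 0.29) and the splicing regulator Esrp1 (−2.17 ± 0.44) fell, and Hoxd9 (1.39 ± 0.20) and Hoxc5 (1.35 ± 0.19) rose. There were 81 rises and 49 falls there, a count that was 7 without pInv replicate 3, 21 without pInv replicate 1, 32 without pInv replicate 2, and between 54 and 72 without WT1 replicate 2 or any WT2 library. Cholesterol synthesis genes Mvd (0.67 ± 0.12) and Msmo1 (0.61 ± 0.11), both on chromosome 8, rose, with 7 of 15 up when adjusted over the list alone. The Hox list had 1 of 15 up and 5 when adjusted over the list alone, ATF4 targets had 2 of 13 up, including Atf4 (0.36 ± 0.07), and epiblast genes had 3 of 13 down, with Lef1 at −0.84 ± 0.13. The neural progenitor genes Sfrp1 (0.74 ± 0.08), Nes (0.70 ± 0.12) and Sox1 (0.86 ± 0.16) rose, of 14. The cholesterol, Hox, ATF4, epiblast and neural progenitor lists were called at adjusted p = 3.24e-06, 8.7e-05, 0.000126, 0.000766 and 0.00745, but adjusted p = 0.0514, 0.0919, 0.127, 0.202 and 0.319 with an estimated correlation. The balance turned with the control line, at 462 rises and 364 falls against WT1 and 195 and 376 against WT2. With the replicate block there were 422 rises and 394 falls in 2i, p53 targets were called (adjusted p = 0.0235, but adjusted p = 0.467 with an estimated correlation), and the cholesterol list had adjusted p = 0.0387 with an estimated correlation. With only WT1 as control Etv4 (0.69 ± 0.13 with both) was at −0.64 and Lef1 at 0.1. Hoxd9 and Hoxc5 lost their calls without pInv replicate 3 (1.37 and 1.33) and Lef1 without pInv replicate 2 or 3 (−0.77 and −0.88). Nes lost it in 3 of 9 fits without 1 library, Msmo1 in 4, Mvd in 5, Sox1 in 6, Atf4, Esrp1 and Etv4 in 7, and Fgf15 in 8.

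In serum pInv had 1 rise, Tenm4 (0.73 ± 0.12), and 7 falls, among them Xlr3a (−2.90 ± 0.42), Aire (−1.88 ± 0.29) and the protease inhibitor A2m (−1.85 ± 0.29), and the count was 2 to 5 without any 1 of 7 of the libraries (WT1 replicate 1 or 2, WT2 replicate 1 or 3, or any pInv library). Xlr3a lost its call in 3 of the 9 fits, Aire in 7, A2m in 8 and Tenm4 in all. The 2-cell-like list was higher in serum with no member passing singly and 9 of 12 up when adjusted over the list alone (list median 1.36, adjusted p = 1.26e-19, and adjusted p = 0.0477 with an estimated correlation). Primitive streak genes were lower as a list (median −0.53, none of 18 passing, adjusted p = 0.00142), but adjusted p = 0.678 with an estimated correlation. Neural progenitor genes were higher as a list in serum (median 0.27, none of 15 passing, adjusted p = 0.000874), but adjusted p = 0.402 with an estimated correlation. In NPCs 2 genes fell, Platr11 and Usp26 (−2.19 ± 0.33), and the count was 6 without WT1 replicate 2 and 1 without pInv replicate 1 or 2, WT2 replicate 2 or 3, or WT1 replicate 3, with Usp26 not called in 6 of the 9 fits. Naive genes were lower as a list in pInv NPCs (median −0.58, none of 15 passing, adjusted p = 3.7e-05), but adjusted p = 0.378 with an estimated correlation. Y-linked genes were lower as a list too (median −0.97, 3 of 4 down when adjusted over the list alone, adjusted p = 1.03e-05), but adjusted p = 0.0816 with an estimated correlation, and feeder genes moved the same way (median −0.3, adjusted p = 0.0332), but adjusted p = 0.678 with an estimated correlation. As an interaction between NPCs and serum the inversion changed 1 gene, Cpt1a, which imports fatty acids into mitochondria (−2.05 ± 0.36, lost in 7 of 18 fits without 1 library), and Eomes did not pass (0.49 ± 0.44, adjusted p = 0.898).

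Deletion and inversion were set against each other to separate loss of the promoter from its orientation. Eomes did not differ past the threshold in 2i (−0.41 ± 0.14, adjusted p = 0.15) or serum (−0.56 ± 0.25, adjusted p = 0.63), and in NPCs it was higher in pKO (2.87 ± 0.43, adjusted p = 0.00597), although without pInv replicate 3 it was 2.66 with adjusted p = 0.0528. Tdgf1 (2.59 ± 0.23, adjusted p = 4.87e-05), Cubn (3.31 ± 0.53) and Nodal (2.30 ± 0.37) were higher in pKO NPCs, as were Foxa2 (6.44 ± 1.16), Fgf8 (4.86 ± 0.81) and T (5.20 ± 1.00). The calls for Nodal and Fgf8 were lost without pInv replicate 3 (values 2.4 and 4.67), and those for Foxa2 and T without any 1 of the 3 pInv libraries. In NPCs 65 genes were higher and 62 lower, with 16 calls without pInv replicate 3 and 49 to 70 without pInv replicate 1 or 2, pKO1 replicate 1 or 3, or pKO2 replicate 2. Primitive streak genes were higher for 2 of 14 and for 10 when adjusted over the list alone (list adjusted p = 1.22e-11, but adjusted p = 0.0989 with an estimated correlation). Nodal pathway genes were higher for 4 of 11 and for 8 when adjusted over the list alone (list adjusted p = 3.05e-09, but adjusted p = 0.0514 with an estimated correlation). The 2-cell-like list was higher with 4 of 11 passing (adjusted p = 3.97e-16, and adjusted p = 0.0469 with an estimated correlation). The neuropeptide gene Penk (−1.98 ± 0.37) and the synaptic organiser Cbln1 (−2.05 ± 0.37) were lower, and the Y-linked gene Ddx3y was higher (1.66 ± 0.32). Penk lost its call without pInv replicate 2 or 3, Cbln1 without pInv replicate 1 or 3, and Ddx3y without any 1 of the pInv libraries.

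In 2i 131 genes were higher in pKO than in pInv and 360 lower, 57.8% of the latter on chromosome 8. Lin28a (1.28 ± 0.21) and Lef1 (1.09 ± 0.13) were higher, with the receptor gene Ror1 (1.94 ± 0.37, or 1.54 and not called without pInv replicate 2), and Hoxa10 (−2.17 ± 0.35), Hoxd9 (−1.27 ± 0.20) and Nes (−0.78 ± 0.13) lower. Hox genes were lower for 3 of 15 and cholesterol synthesis genes for 3 of 15, with Mvd at −0.87 ± 0.12, and hypoxia and glycolysis genes were higher for 4 of 15, with Egln3 at 0.95 ± 0.12. These lists were called at adjusted p = 3.93e-06, 0.000454 and 0.000666, but adjusted p = 0.0514, 0.124 and 0.402 with an estimated correlation. Neural progenitor genes were lower for 4 of 14 (list adjusted p = 0.0271, but adjusted p = 0.402 with an estimated correlation), which was lost with the replicate block (adjusted p = 0.0541), whereas feeder and interferon genes were then called (adjusted p = 0.000577 and 0.000477, but adjusted p = 0.451 and 0.242 with an estimated correlation). The block gave 1301 calls, and leaving out pInv replicate 2 or 3 gave 162 or 123, with 283 to 320 without pInv replicate 1, pKO1 replicate 2, or pKO2 replicate 2 or 3. In serum 12 genes were higher in pKO and 13 lower, with 1 call without pInv replicate 3, 3 without pInv replicate 1, and 11 or 12 without pInv replicate 2 or pKO1 replicate 1 or 2. The naive factor Tbx3 (1.25 ± 0.16), the hypoxia factor Epas1 (1.68 ± 0.21) and the autoimmune regulator Aire (2.29 ± 0.29) were higher there, and the RNA export gene Nxf3 (−2.23 ± 0.28) and the proteasome gene Psmb10 (−1.55 ± 0.23) were lower. The Tbx3 and Psmb10 calls were lost without pInv replicate 1 or 3, and those for Epas1, Aire and Nxf3 without pInv replicate 3. The 2-cell-like list was higher in serum (median 0.97, adjusted p = 1.12e-09), but adjusted p = 0.112 with an estimated correlation, the primitive streak list lower (median −0.9, adjusted p = 0.000186), but adjusted p = 0.674 with an estimated correlation, and feeder genes higher (median 0.42, adjusted p = 0.0022), but adjusted p = 0.754 with an estimated correlation.

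The knockdown lines asked what a lower level of the transcript does. The series text names Cas9 for them and the sample labels name dCas9, so whether these lines carry edits or only repression of the locus was not settled. Eomes was 37.9 ± 17.7 CPM in KD against 44.5 ± 15.3 in Ctrl in serum (SD, n = 6 and 3, log2 fold change −0.24 ± 0.35, adjusted p = 1) and 10.5 ± 14.6 against 5.72 ± 3.76 in NPCs (0.58 ± 0.73, adjusted p = 0.999). KD2 replicate 1 alone reached 40.3 CPM in NPCs, and without it the fold change was −0.31, while without Ctrl replicate 1 the serum value was 0.06. Platr11 itself missed the threshold without the block (−3.39 in serum, adjusted p = 0.18, and −2.85 in NPCs, adjusted p = 0.138) and passed with the replicate block (adjusted p = 6.21e-06 and 2.09e-05). No other value of Eomes, Cmc1 or Golga4 passed in either state. The edgeR test called 0 of 13644 genes in serum and 0 of 13466 in NPCs, with 138 and 181 genes at an unadjusted p under 0.05, where chance gives 682 and 673. These fits, and that of the interaction below, held no block although the numbers pair the libraries. Counts below chance are therefore no evidence that knockdown had no effect. DESeq2 called 1 and 2 genes and the replicate block 1 and 2, and the serum count was 1, Platr11, without KD1 replicate 3, as was the NPC count without Ctrl replicate 1. No list had a member called, although hypoxia genes in serum (median −0.11, adjusted p = 0.00726) and feeder genes in both states (0.35 in serum, adjusted p = 0.0352, and −0.28 in NPCs, adjusted p = 0.0118) were called as lists, with adjusted p = 0.678, 0.831 and 0.678 with an estimated correlation. The block added primitive streak, extraembryonic endoderm and Wnt lists in serum (adjusted p = 0.0275, 0.0478 and 0.0424, but adjusted p = 0.656, 0.451 and 0.565 with an estimated correlation) and, in NPCs, neural progenitor, Hox, hypoxia, ATF4 and naive lists (adjusted p = 0.000703, 0.00442, 0.00616, 0.00774 and 0.0235, but adjusted p = 0.217, 0.588, 0.513, 0.517 and 0.598 with an estimated correlation). As an interaction between NPCs and serum the knockdown changed 0 of 14374 genes with edgeR (83 at an unadjusted p under 0.05, 719 by chance, 4 with DESeq2), and Eomes was at 0.83 ± 0.84 (adjusted p = 1), or −0.1 without KD2 NPC replicate 1. Its lists were feeder genes (median −0.6, adjusted p = 7.48e-05), epiblast genes (adjusted p = 0.0246) and primitive streak genes (median 0.6, adjusted p = 0.0278), with adjusted p = 0.674, 0.454 and 0.678 with an estimated correlation, to which the block added ERK targets, interferon and neural progenitor genes (adjusted p = 0.0255, 0.0264 and 0.0104, but adjusted p = 0.52, 0.392 and 0.171 with an estimated correlation).

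Comparisons that share WT libraries correlate by construction, so each was set beside simulated unchanged groups. Over genes, which are not independent replicates, pKO and pInv fold changes correlated at r = 0.427 in 2i, 0.615 in serum and 0.437 in NPCs, against 0.399, 0.397 and 0.406 in 20 simulations, and their covariances were 0.0575, 0.104 and 0.128 against 0.0288, 0.0297 and 0.0477. With WT1 for one and WT2 for the other, r was 0.088 and −0.214 in 2i, 0.497 and 0.097 in serum, and 0.249 and −0.035 in NPCs. In 2i the pKO and pInv calls shared 22 rises and 28 falls, where independent lists would share 2.66 and 2.87, with 4 genes opposite. With WT1 for pKO and WT2 for pInv they shared 12 and 13 (independent 2.07 and 9.37) with 26 opposite, and with WT2 for pKO and WT1 for pInv 14 and 23 (independent 35.2 and 44.3) with 381 opposite, so the overlap depended on the control lines. The pKO1 and pKO2 fold changes correlated at 0.547, 0.563 and 0.391 (simulated 0.326, 0.322 and 0.333), with covariances of 0.101, 0.158 and 0.19 (simulated 0.029, 0.0294 and 0.048) and split-control values of 0.028 and 0.174, 0.302 and 0.401, and 0.052 and 0.315. KD1 and KD2 correlated at 0.273 in serum (simulated 0.5) and 0.593 in NPCs (simulated 0.491), with covariances of 0.0321 and 0.0521 (simulated 0.0667 and 0.0797). These simulations held no replicate effect, although the numbers pair the libraries in 2i and for knockdown. Neither they nor those that follow held differences between lines, although WT1 and WT2 differed at 2536 genes in 2i. Differences between the shared WT lines and the others could raise r and covariance without an effect of the deletion. With shared replicate effects in the simulated groups, added after seeing the data, the simulated r for KD1 and KD2 was 0.497 and 0.498 and the covariance 0.0313 and 0.0264, and in 2i they were 0.4 and 0.0144 for pKO with pInv and 0.327 and 0.0145 for pKO1 with pKO2. Without shared libraries, pKO and KD correlated at 0.247 in serum and 0.011 in NPCs.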

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

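The items below stood out because an interaction test found the effect to differ between NPCs and serum, and every test of an explanation in this part was chosen after the result was seen. The promoter deletion had a different effect at 641 genes. The genes with the largest differences upward were Evx1 (8.08), Cdx2 (6.85), the antisense transcript Evx1os (6.64), Dkk1 (6.32) and the near-identical copies Sprr2a1 and Sprr2a2 (6.19 each, with uncertain reads). Those with the largest differences downward were Adam33 (−4.08), Tslp (−4.07), Vwf (−3.89), Sp100 (−3.77), Gsto2 (−3.24) and Rbm44 (−3.13). Eomes differed by 3.91 and Plcd1, a gene near Eomes, by −1.02. For the inversion 1 gene differed, Cpt1a (−2.05).

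For higher Eomes and primitive streak genes in pKO NPCs, 3 explanations were weighed, with tests chosen after the result was seen. Undifferentiated cells left in the pKO cultures would have to be 32% of the culture, at the level of WT serum cells, to give the Eomes value. This needs a naive pluripotency median of 2, whereas the median was 0.12 and 0 of 15 members reached the needed value. Cells like those of the WT serum cultures were thus excluded as the whole cause. Undifferentiated cells with low naive genes stayed open, because the naive list cannot show them. Core pluripotency genes, which such cells could raise, were called higher as a list in pKO NPCs, though not with an estimated correlation. Against loss of the Platr11 transcript as such, pInv NPCs lack it too and Eomes was 2.87 higher in pKO than in pInv, but this stays open, because pInv is 1 line and the call was lost without pInv replicate 3 (2.66, adjusted p = 0.0528). Differences between single cell lines unrelated to the deletion could not be told apart from its effect, because with the lines as replicates Eomes had an adjusted p of 0.262.

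For lower chromosome 11 genes in the pKO lines, the tests were chosen after the result was seen. An effect of the deletion on chromosome 11 in 2i could not be told from a difference between lines. The WT lines differed from each other by −0.35 there, against −0.22 between pKO and WT. In serum and NPCs such an effect could not be told either, as the lowest WT library lay 0.19 above the highest pKO library in NPCs. Against a chromosome copy number fixed in each line, the median log2 fold change between WT1 and WT2 went from −0.35 in 2i to −0.07 in NPCs. The differences in median deviation over their library pairs did not overlap (−0.376 to −0.332 in 2i and −0.165 to 0.027 in NPCs). Such a copy number was not excluded, because it need not shift RNA alike in both states, and only the WT lines were compared. A copy number in a share of the cells that differs between cultures could not be told apart from an effect of the deletion in serum and NPCs: 84.3% of chromosome 11 genes lay below 0 in NPCs, against 37.4% to 61.9% on 17 other chromosomes, which either would give, and no DNA was measured.

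For lower Eomes and primitive streak genes in pKO cells in serum, the tests were chosen after the result was seen. With the feeder score as a covariate Eomes was at −0.81 ± 0.18 (SE, adjusted p = 0.0201), while the feeder list median went from 0.77 to 0.01. Primitive streak genes then had a median of −0.98 with 3 down. With the feeder score and replicate block Eomes was at −0.96 ± 0.3 (adjusted p = 0.423), and primitive streak genes had a median of −1.76 with 1 down. Both fits kept the direction, which argues against feeder RNA in the serum libraries as the whole cause. Feeder RNA was not excluded, because the Eomes call was lost with the block. Fewer differentiating cells of every lineage would need the neural progenitor genes to fall about as far as the primitive streak genes. Their median was 0.03 with the feeder score (quartile range 0.63, 7 of 15 below 0) against −0.98, and 0.27 without it (quartile range 0.97) against −1.36. Neural progenitor genes thus did not fall with them. The explanation was not excluded, because most of these genes were lower in serum than in NPCs and may have had little room to fall. Definitive endoderm genes were lower too.

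Whether other splits of the same libraries call as many genes was asked of each comparison, with tests chosen after the result was seen. These splits used a fit with 1 mean per arm instead of 1 per line, in which the real grouping called fewer genes than in the results above, such as 91 against 1273 for pKO in 2i, 437 against 847 in serum, 718 against 1171 in NPCs, 2 against 130 for pInv in 2i and 127 against 641 for the pKO interaction. For pKO few splits of single libraries called as many genes as the real one, which is counted among them. This held in 2i (1 of 100 splits, real 91, highest other 1), in serum (1 of 100, real 437, highest other 1) and in NPCs (2 of 100, real 718, highest other 1821). None of the other splits drawn for pKO kept the lines whole, so these counts do not exclude chance between lines. In the fit by line, in 2i, WT1 and pKO2 against WT2 and pKO1 called 1467 genes and WT1 and pKO1 against WT2 and pKO2 1007, beside 1273 for genotype, so a grouping of lines unrelated to the deletion was not excluded there. The same groupings called 189 and 3 in serum, beside 847, and 505 and 16 in NPCs, beside 1171. So few groupings of whole lines exist that one unrelated to the deletion was not excluded in serum or NPCs either. Eomes did not pass there with the lines as replicates. Chance was excluded for WT serum against 2i (1 of 100, real 8933, highest other 0) and WT NPCs against serum (1 of 100, real 9485, highest other 3835). For pKO against pInv in NPCs 3 of 84 splits called as many (real 18, highest other 453, which parts pKO2 from the rest). A split of the libraries numbered 1 from the rest called 56. Most splits of single libraries thus called fewer genes, but a difference between lines called more than the genotype did. With 1 pInv line, chance between lines was not excluded.

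In 2i the numbers pair the libraries, so the real split was also set against splits with the numbers balanced between the arms, with tests chosen after the result was seen. For pInv in 2i 4 of 84 splits called as many (real 2, highest other 1037, the libraries numbered 1 from the rest), but so did 2 of the 26 other balanced splits (highest 773), and chance was not excluded. For pKO against pInv in 2i 3 of 84 did (real 248, highest other 1028, a split by replicate number), but so did 1 of the 26 other balanced splits (highest 441), and chance was not excluded there either. With the replicate block these comparisons had 816 and 1301 calls in the fit by line. Nor was chance excluded for pInv in serum (12 of 84, real 1, highest other 983, the libraries numbered 3 from the rest) or NPCs (7 of 84, real 1, highest other 808), for pKO against pInv in serum (6 of 84, real 1, highest other 1345, by replicate number) or for the pKO interaction (6 of 100, real 127, highest other 1582). Splits that call several times the real count point to structure among the samples other than genotype. Where the real count was 0 the count of splits was fixed in advance and says nothing on chance, which holds for knockdown in serum (84 of 84, highest other 2027), in NPCs (84 of 84, highest other 5482, the libraries numbered 1 from the rest) and for the pInv and knockdown interactions (100 of 100 each, highest other 872 and 2304).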

How the results depend on the processing

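Each genotype has at most 2 lines and pInv has 1, so line and genotype cannot be fully separated, and nothing states how independent the 3 libraries of a group are. The values below moved or lost a call under another setting, and the cause was not tested.

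With the lines as replicates pKO gave 1 call in 2i (Eomes −1.01), 12 in serum (Eomes −1.17) and 0 in NPCs (Eomes 2.71), and pInv gave 1, 0 and 0. With only WT1 as control pKO gave 495 calls in 2i, 168 in serum and 363 in NPCs, and pInv gave 826, 58 and 38. In 2i this put Usp17le at 0.2, Fbln1 at −0.05, Etv4 at −0.23, Tex19.1 at 0.32 and Tfcp2l1 at −0.07 for pKO, and Eomes at −0.84, Etv4 at −0.64 and Lef1 at 0.1 for pInv, and in serum Dnmt3l at −0.24 for pKO. With only WT2 as control pKO gave 2756 calls in 2i and 766 in NPCs, and pInv gave 571 in 2i (Mthfd2 −0.03), 4 in serum and 1 in NPCs (Eomes 0.59). Within WT states, only WT1 put Ddx3y at −0.1 for serum against 2i and Usp17la at 0.22 for NPCs against serum.

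With only pKO1 there were 130 calls against WT in 2i and 6, 0 and 17 against pInv in 2i, serum and NPCs. It put Cmc1 at −0.02 and Dnmt3l at −0.02 in serum and Dnmt3l at −0.73 in NPCs against WT. With only pKO2 there were 415 calls in serum (Eomes −0.97, Golga4 −0.13) and 712 in NPCs against WT, and 777, 86 and 409 against pInv in the 3 states. With only KD2 Golga4 was at −0.01 in serum, and with only KD1 Eomes was at −0.35 in NPCs.

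With DESeq2 the calls were 433 for pInv in 2i (Eomes −0.57), 1343 for pKO in serum, 46 for pInv in serum, 109 for pKO against pInv in serum, 1896 for pKO in NPCs, 55 for pInv in NPCs and 475 for pKO against pInv in NPCs. It gave 1 and 2 for knockdown in serum and NPCs, and 983, 11 and 4 for the pKO, pInv and knockdown interactions. With no low-count filter pInv gave 77 calls in 2i and 6 in NPCs, and knockdown in serum 1. Of 448 list tests 136 were called with the preset correlation, 156 with the block and 6 with an estimated correlation.

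With the replicate block the calls were 2925 for pKO, 816 for pInv (Eomes −0.57) and 1301 for pKO against pInv in 2i, and 1 and 2 for knockdown in serum and NPCs, and the block changed no other call on Eomes in these paired sets. Where numbers pair less well the block gave 2888 (1504 up and 1384 down), 25 and 166 in serum for pKO, pInv and pKO against pInv, 7 for pInv and 256 for pKO against pInv in NPCs, and 1603 and 20 for the pKO and pInv interactions. Libraries correlated best with their own number within a state for 15 of 15 in serum, 12 of 15 in NPCs, 18 of 18 in the WT set and 42 of 45 in the joint set, and across states for 12 of 18 and 17 of 45.

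With the feeder score as a covariate the calls in 2i were 2426 for pKO, 659 for pInv (Eomes −0.56) and 1035 for pKO against pInv, in serum 501, 17 and 53, and 1 for knockdown in serum. With the feeder score and replicate block they were 2924, 641 (Eomes −0.59) and 738 in 2i, 25 for pKO in serum (Eomes −0.96, Cmc1 −0.17, Golga4 −0.03), 14 for pInv in serum and 2 for knockdown in serum (Eomes 0.23, Golga4 −0.09). Without the genes of chromosomes 8 and 11 there were 45 calls for pInv and 184 for pKO against pInv in 2i, 367 for pKO in serum, 612 for pKO in NPCs and 62 for pKO against pInv in NPCs. Without the libraries numbered 1 there were 450 for pInv and 905 for pKO against pInv in 2i and 1 for knockdown in NPCs. Without the libraries numbered 3 there were 1597 for pKO in serum (Golga4 −0.02), 3 for pInv in serum (Cmc1 0.07), 6 for pKO against pInv in serum and 1 for knockdown in serum.

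Leaving out 1 library at a time, the calls in 2i ran from 704 to 1764 for pKO, 7 to 176 for pInv and 123 to 350 for pKO against pInv. In serum they ran from 307 to 1370, from 2 to 10 (Cmc1 −0.12 to 0.05) and from 1 to 28. In NPCs they ran from 529 to 1921 (Golga4 −0.09 to 0.03), from 1 to 6 (Eomes −0.25 to 0.15) and from 16 to 111 (Eomes 2.52 to 3.06). For knockdown they ran from 0 to 1 in serum (Eomes −0.61 to 0.06) and from 0 to 1 in NPCs (Eomes −0.31 to 1.29, Cmc1 −0.04 to 0.21, Golga4 −0.04 to 0.22). For the interactions they ran from 291 to 1086 for pKO and 0 to 8 for pInv, and Eomes ran from −0.1 to 1.53 for knockdown.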

Other observations

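Several groups in the pKO interaction have not been described above. Cholesterol synthesis genes had a higher effect of the deletion in NPCs than in serum for 3 of 15 (median 0.19, list adjusted p = 0.000356, but adjusted p = 0.147 with an estimated correlation), trophoblast genes for 2 of 10 (median 0.6, adjusted p = 0.00886, but adjusted p = 0.412 with an estimated correlation) and epiblast genes for 4 of 14 (median 0.45, adjusted p = 0.00458, but adjusted p = 0.352 with an estimated correlation). Genes near Eomes went the other way as a list (median −0.84 over 9, adjusted p = 0.00323, but adjusted p = 0.0989 with an estimated correlation), with Plcd1 alone passing (−1.02 ± 0.30). For the inversion, naive pluripotency genes had a lower effect in NPCs than in serum (median −0.73, none of 15 passing and 8 down when adjusted over the list alone, list adjusted p = 1.49e-08, but adjusted p = 0.0971 with an estimated correlation).

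Hypothesis: the promoter sequence, rather than the transcript, restrains Eomes in NPCs. This would be in line with the value of 2.87 for Eomes in pKO against pInv NPCs, where both lack Platr11, and a test would be to restore the transcript from elsewhere in pKO cells and to derive more inversion lines, since pInv is a single line and the call was lost without pInv replicate 3 (2.66).

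Hypothesis: the higher primitive streak genes in pKO NPCs follow from Eomes or Nodal in a part of the cells. The naive pluripotency median of 0.12 may leave room for a mesendoderm fraction without naive undifferentiated cells, and single-cell counts or staining of EOMES and SOX1 in pKO NPCs would tell.

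Hypothesis: the cultures differ in the share of cells with another copy number of chromosome 11. The 84.3% of chromosome 11 genes below 0 in pKO NPCs could come from such a difference. Against a copy number fixed in each line, the WT lines differed by −0.35 in 2i and −0.07 in NPCs, but this does not exclude it. On chromosome 8 the WT lines differed about alike in 2i, serum and NPCs (−0.41, −0.38 and −0.36). Karyotypes or DNA sequencing of the 5 lines would tell.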
